A study of Arabidopsis thaliana with 6 samples.

How the data were processed

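Leaf RNA of 2-week-old Arabidopsis thaliana seedlings was hybridised to Affymetrix ATH1 arrays, which carry sets of short oligonucleotide probes for most genes of the genome known when they were designed. Per the labels' protocols, plants had 16 h of light at 22 °C and 8 h of dark at 20 °C after 3 days of cold at 4 °C, and the sampled seedlings grew on agar with 1.5% sucrose. The 6 arrays fall into 2 groups of 3, the essp3 mutant and the wild type with the beta-conglycinin promoter reporter. Per the series' design text, the arrays of a group come from independent biological replicates. The labels call the allele by 2 names, and which is right is not given in the sources used here.

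The intensity values were deposited by the authors as MAS5 signals, per the submitters' processing notes, and mean-scaled, per the file headers. Their mean over the 22808 probe sets was 1000 on every array. The deposited table also holds detection calls (Present, Marginal or Absent) made by the authors with MAS5, per the file headers. The deposited ratio per probe set is the authors' mean of the mutant signals over their mean of the wild-type signals, per the file headers. The deposited p-value is from the authors' unpaired test at a threshold of 0.05, unadjusted, per the file headers, and a further mark made by the authors says which probe sets passed. The kind of test, the MAS5 version and the genome annotation behind the locus codes are not given in the sources used here. The value table of the series matrix held the same intensity as the deposited table in all 136848 cells. Each signal and detection call column of the deposited table was matched to a sample.

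After 62 control probe sets were left out, 22746 remained. Of these, 22591 had a locus code and 155, mostly of the organelle genomes, had none. Symbols were taken from a table of RefSeq gene names of the assembly TAIR10.1, in which 22091 locus codes were found and 500 were not; a gene without a symbol keeps its locus code. No coordinates are given because the array's build is not given in the sources used here. The suffix of 1061 probe sets marks a possible match to several genes, and such probe sets are named only as members of a fixed list, with that stated.

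Signals were used on the log2 scale with no further normalization. Signals of 0 were set to the smallest signal above 0 on the same array. Probe sets called Present on at least 2 of the 6 arrays were tested, 14313 in all. The test was limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, mutant against wild type, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over 19 lists, and again with an estimated correlation. Where no array of a group was called Present, the fold is given as "at least": the mean log2 signal of the brighter group against, for each array of the dimmer group, the higher of its own signal and the lowest Present signal of that array (26.3 to 49.2). For FT, RVE1, RVE8 and VSP1 this fold lay above the ratio of the mean signals, so the mutant signal is given in place of a bound. The bounds allow for the lowest Present signal but not for the spread between arrays, so the true fold may be smaller. The adjustment of the authors' p-values and the bounds without single arrays were chosen after the results were seen. The smallest p that an exact test of 3 against 3 arrays allows is 0.1, so single genes were tested only in the model across all probe sets. Figures were drawn with matplotlib 3.10.9.

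The genes named were fixed by a rule before the data were examined: BRM; the 10 largest rises and 10 largest falls by fitted log2 fold change among probe sets past the threshold, of 1 gene, whose groups did not overlap; from each list up to 4 members past the threshold, by size, or the 2 with the largest difference where none passed; and LEC1, LEC2, FUS3, ABI3, the 2S albumins and the cruciferins in any case. PYK10, IRT1 and the iron and copper genes fall outside the rule and were chosen after values were seen; the second set of clock genes was chosen before its own values were seen. The lists cover seed storage, oil body, late maturation and embryo regulator genes, SWI/SNF and Polycomb genes, flowering, leaf polarity, photosystems, defence, hormones, cell division, flavonoids, senescence, the clock, heat, touch, root and guard cell markers.

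The test was tried on simulated data with known changes in the 14313 probe sets. It recovered 32.8% of 67 changes of 1.5-fold, 77.6% of 67 changes of 2-fold and 93.9% of 66 changes of 4-fold, and called 7 of 14113 unchanged probe sets. Simulated noise was independent between probe sets, and far fewer probe sets were changed than passed in the real comparison (27.1%). These rates may therefore not hold for the real arrays. The number of arrays limits the precision. Alternatives tried were quantile normalization, median centring, an offset of 16, other filters, other spread priors, array weights, the replicate number as a block, other thresholds, and leaving out each array in turn.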

Results

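Transcript levels were measured on 6 ATH1 oligonucleotide arrays of Arabidopsis leaf RNA, 3 from the essp3 mutant and 3 from the wild type. The essp3 mutant carries an allele of BRM, the gene of the BRAHMA chromatin remodelling ATPase. The wild type carries a reporter in which the promoter of a beta-conglycinin seed storage gene drives beta-glucuronidase (GUS). The seedlings were 2 weeks old and grown on plates with 1.5% sucrose. On the 6 arrays, 56.4% to 60.3% of probe sets were called Present. The labels give the allele under 2 different names, so it is called the mutant here. The comparison asks which genes, seed genes above all, are expressed differently in leaves when BRM is mutated.

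Some seed storage protein genes were detected in mutant leaves and not in wild-type leaves. The cupin gene AT4G36700 was called Present on all 3 mutant arrays and Absent on all 3 wild-type arrays, with a signal of 1095 ± 233 (SD, n = 3) in the mutant, at least 37.1-fold above the wild type (limma, adjusted p = 4.6e-07). SESA2 and SESA5, which encode 2S albumins, showed the same calls and rose at least 5.83-fold (adjusted p = 0.0169) and at least 6.42-fold (adjusted p = 0.00103). The 95% intervals of the fitted folds of SESA2 and SESA5 began lower, at 5.15 and 3.54. AT4G36700, SESA2 and SESA5 were all 3 measured members of the seed storage list, and all 3 also passed when adjusted over the list alone. They entered the test only because they were Present in the mutant, so the direction of the list's result (camera, adjusted p = 0.00366; adjusted p = 0.161 with an estimated correlation) was set by the filter. With no filter, 4 of all 13 members rose and none fell, SESA3 being the further one although Absent on all 6 arrays (camera, adjusted p = 0.0411). SESA2 lost its call when any 1 of the 3 mutant arrays was left out, with an adjusted p of up to 0.186.

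Most other seed genes were not detected in either group. The other 10 storage genes were not called Present on 2 arrays and were not tested. The 2S albumin genes SESA1, SESA3 and SESA4, the cruciferin genes CRA1 and CRU2, and AT1G03890 were Absent on all 6 arrays, as were LEC1 and ABI3, regulators of embryo development and seed maturation. LEC2 and FUS3, regulators of the same programme, and the cruciferin gene CRU3 were called Marginal on 1 mutant array and Absent elsewhere. FUS3 had a signal of 96.9 ± 44.7 (SD, n = 3) in the mutant and 36.4 ± 16.99 (SD, n = 3) in the wild type, and was not tested.

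**Figure D1:**
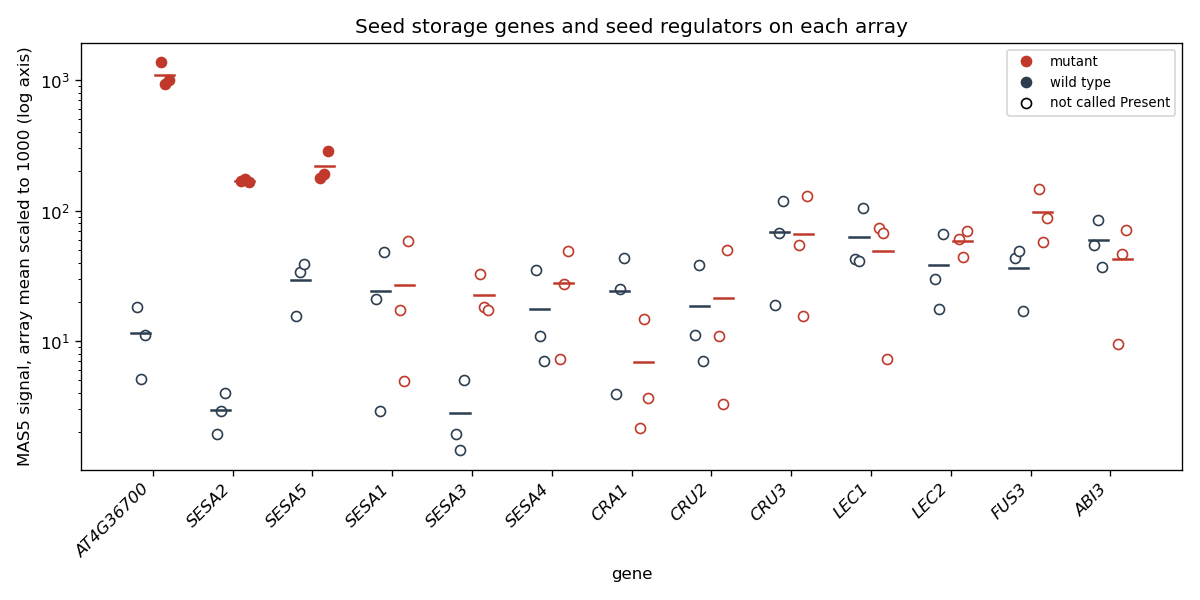
Signal on each array (log axis, array mean scaled to 1000) for seed storage genes and seed regulators, with 3 mutant and 3 wild-type points per gene, open where not called Present, and a line at each group mean. AT4G36700, SESA2 and SESA5 are Present on all 3 mutant arrays and lie above all 3 wild-type arrays.

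Other seed lists held few measured genes. Of 4 measured late maturation genes, RAB18, a dehydrin gene, rose by 0.86 ± 0.19 (log2, SE; adjusted p = 0.0045) and LEA14 fell by 0.44 (adjusted p = 0.0303), with the same 2 called when adjusted over the list alone; the list did not pass (camera, adjusted p = 0.825). None of 5 measured embryo transcription factor genes passed, over all probe sets or adjusted over the list alone (camera, adjusted p = 0.942), with log2 differences of 0.65 for WOX2 and -0.30 for BZIP25; without mutant array 3, BZIP25 passed at -0.62 (adjusted p = 0.0151). The oil body list had 2 measured members, OLEO3 (-0.53, adjusted p = 0.588) and TAG1 (-0.28, adjusted p = 0.293), and was not tested as a set.

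BRM itself was called Present on all 6 arrays. Its signal was 917 ± 154 (SD, n = 3) in the mutant and 768 ± 104 (SD, n = 3) in the wild type, a log2 difference of 0.25 ± 0.17 (SE) that did not pass (adjusted p = 0.285). The labels do not say that the mutation removes the transcript, so this level does not check them. Of 11 measured genes of SWI/SNF subunits, the complex BRM belongs to, none passed, over all probe sets or adjusted over the list alone (camera, adjusted p = 0.993). The related ATPase gene SYD differed by 0.44 ± 0.16 (adjusted p = 0.058) and BSH by -0.35 ± 0.17 (adjusted p = 0.137). Among 14 measured genes of Polycomb and other repressors of seed genes, 1 rose, DRIP2, by 0.82 ± 0.22 (adjusted p = 0.0137), also adjusted over the list alone (camera for the list, adjusted p = 0.942).

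The 10 rises named by the rule on fitted log2 fold change include AT4G36700 and SESA2; fitted values against an Absent group are not measured sizes, so no order is given among them. AT3G02480, annotated as abscisic acid responsive, was Present on all 3 mutant arrays and Absent on all wild-type arrays, at least 39.9-fold higher (adjusted p = 3.5e-07). The transcription factor genes bHLH39 and BHLH101, which act in the response to iron deficiency, rose by 7.28 ± 0.75 and 6.22 ± 0.80 on the log2 scale (SE; adjusted p = 1.6e-05 and 8.7e-05), and AT1G47400 rose by 6.52 ± 0.32 (adjusted p = 2.3e-08). All 3 were called Present on 1 wild-type array, and without wild-type array 1 or 2 bHLH39 stood at 5.98 or 8.30, and without wild-type array 3 or 2 BHLH101 stood at 4.81 or 7.23. The fitted sizes of all 3 thus rest partly on Absent values. On wild-type array 2, where they were Present, the signals were 130 for bHLH39, 173 for BHLH101 and 210 for AT1G47400. Their mutant means were 4918, 3185 and 9232. AT1G02200, AT2G15020, AT1G12070 and the cysteine proteinase gene AT2G27420 were Absent on all wild-type arrays and rose at least 14.4-fold, 19.3-fold, 7.71-fold and 6.18-fold, bounds that went down to 12.8, 15.6, 7.32 and 5.03 without single arrays.

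The 10 falls named by the same rule are likewise without order. NAC1, a transcription factor gene of auxin signalling, was Present on all 3 wild-type arrays and Absent on all mutant arrays, at least 7.65-fold lower (adjusted p = 0.000135). GH3.3, which encodes an auxin-conjugating enzyme, was Present on 2 wild-type arrays and Absent on all mutant arrays and fell at least 5.61-fold (adjusted p = 0.0158), or 4.02-fold without mutant array 2 and 8.65-fold without wild-type array 1. LAX1, an auxin influx carrier gene, fell by 2.96 on the log2 scale (adjusted p = 2.3e-08). BCAT-2, of branched-chain amino acid breakdown, fell by 2.98, the sugar transporter gene SWEET10 by 2.92, and the peroxidase gene AT2G37130 by 3.32. HRS1, AT3G19550 and AT3G24450 were Absent on all mutant arrays and fell at least 6.23-fold, 3.95-fold and 2.73-fold, bounds that went down to 5.10, 3.65 and 2.51 without single arrays, and the pyruvate kinase family gene AT3G49160, Absent on 1 mutant array, fell by 3.47, or fell by 4.26 without mutant array 2 and fell by 2.26 without mutant array 3.

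In all, 3873 of 14313 probe sets tested (27.1%) passed the threshold, 1965 higher and 1908 lower in the mutant. Of these, 976 changed at least 2-fold, 556 upward and 420 downward. The 3 mutant values lay on one side of the 3 wild-type values for 5952 probe sets (41.6%; chance gives 10%). The authors' deposited table marks 5056 probe sets at its unadjusted threshold, 2642 higher and 2414 lower; 4548 of them were among those tested, and 3436 were called in both, in the same direction. With the authors' p-values adjusted by Benjamini-Hochberg 919 passed; 874 of them were among those tested, and 837 were called in both, in the same direction.

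Leaf senescence genes fell. Of 7 measured members 5 fell and 1 rose, with the same counts when adjusted over the list alone (camera, lower in the mutant, adjusted p = 0.00366; adjusted p = 0.161 with an estimated correlation). NAP and NAC6, transcription factor genes that promote senescence, fell by 2.62 (adjusted p = 1.3e-06) and 2.02 (adjusted p = 3.1e-05) on the log2 scale, and ASN1, an asparagine synthetase gene induced by darkness, fell by 1.66 (adjusted p = 4.6e-07). SAG29, a sugar transporter gene also used in seeds, went the other way: Absent on all wild-type arrays and at least 8.58-fold higher in the mutant (adjusted p = 0.000665), or 7.36-fold without wild-type array 2.

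Of 15 measured cell division genes 4 rose, none fell and 11 did not pass, with the same counts adjusted over the list alone (camera, higher in the mutant, adjusted p = 0.00366; adjusted p = 0.161 with an estimated correlation). TSO2, a ribonucleotide reductase gene, rose by 2.00 ± 0.11 (log2, SE; adjusted p = 6.9e-08), and MCM3, of the replicative helicase, by 1.04 ± 0.23 (adjusted p = 0.00465). MCM2 (0.88, adjusted p = 0.0224) and the cyclin gene CYCD3;1 (0.82, adjusted p = 0.0143) also rose.

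Clock genes of the morning rose. Of 6 measured members 4 rose and 1 fell, with the same counts adjusted over the list alone (camera, adjusted p = 0.01; adjusted p = 0.521 with an estimated correlation). LHY and CCA1, which encode the morning transcription factors of the clock, rose by 2.65 ± 0.30 and 1.95 ± 0.22 (log2, SE; adjusted p = 3.4e-05 and 3e-05). RVE1 and RVE8 were Absent on all wild-type arrays and Present on all mutant arrays, with mutant signals of 632 ± 109 and 230 ± 28.7 (SD, n = 3), and were called higher (adjusted p = 2e-05 and 0.0011). Of 8 measured evening genes, ELF4 rose by 1.45 while PRR5 fell by 1.44 and GI by 0.80, the same 3 calls adjusted over the list alone (camera, adjusted p = 0.32). The labels used here do not give the hour of harvest.

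Genes of cold and abscisic acid response were higher as a set: 4 of 12 measured members rose and 1 fell, against 4 and 2 adjusted over the list alone (camera, adjusted p = 0.0436; adjusted p = 0.307 with an estimated correlation). COR15B, a cold-regulated chloroplast protein gene, rose by 2.43 ± 0.23 (adjusted p = 8e-06), CBF2, a regulator of cold response, by 0.79 (adjusted p = 0.0258), and HAB1, a phosphatase of abscisic acid signalling, by 0.76 (adjusted p = 0.013); the probe set for KIN1 (1.22) may also match other genes. Touch response genes rose, 4 of 6 and none lower, also adjusted over the list alone (camera, adjusted p = 0.042; adjusted p = 0.254 with an estimated correlation): RHL41 rose by 1.52, WRKY40 by 1.13, STZ by 0.66 and TCH4 by 0.43. HSP70 was the only measured heat shock gene and rose by 2.33 ± 0.20 (adjusted p = 3.8e-06). Without mutant array 1 the cold and touch lists no longer passed (adjusted p = 0.0958 and 0.0621), nor with the stricter Present filter (0.0504 for both) or a spread prior without trend (0.0621 for both), and the cold list did not pass with no filter (0.0721).

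**Figure D2:**
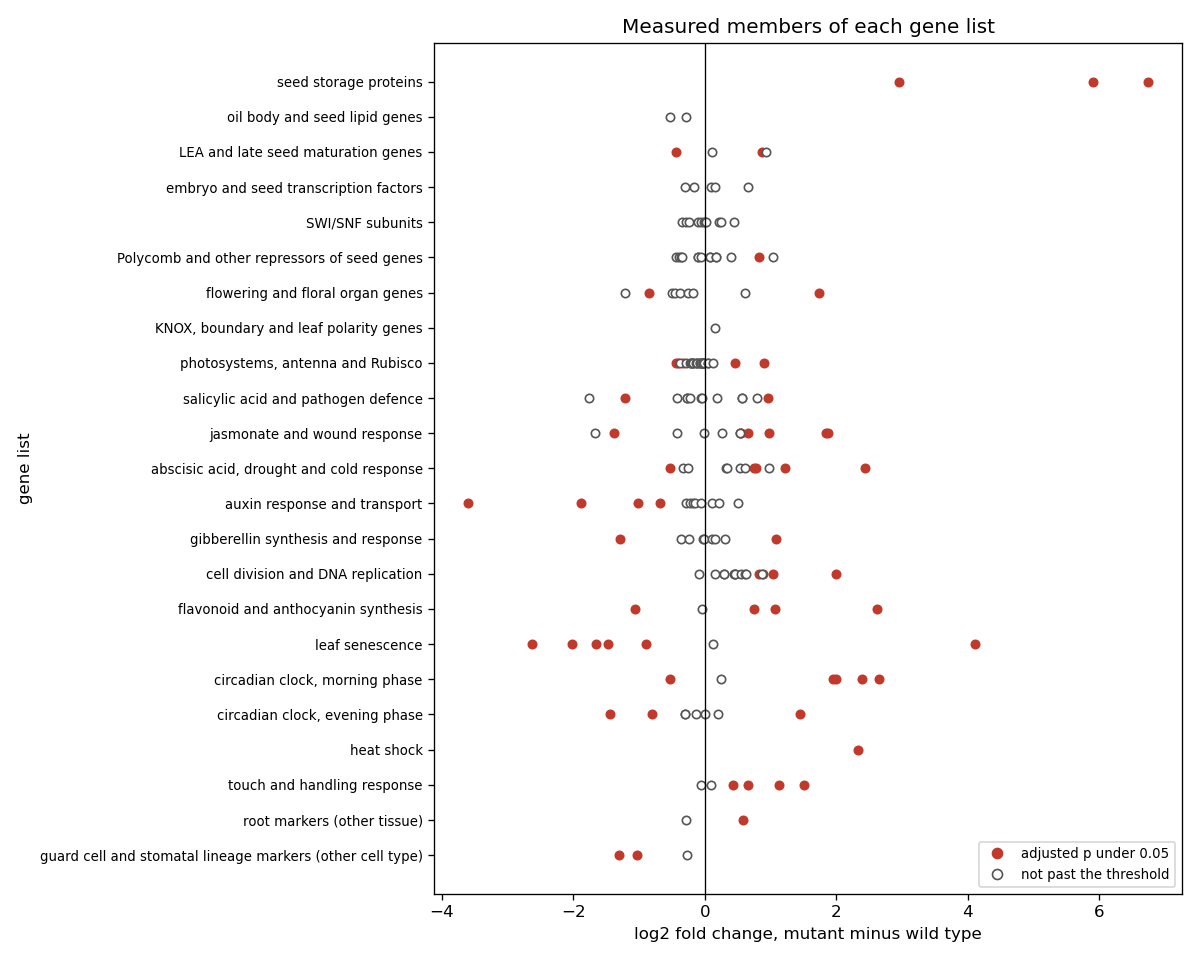
Log2 fold change, mutant minus wild type, of each measured member of the gene lists, filled where the adjusted p was under 0.05 and open elsewhere. Values against a group called Absent are fitted and not measured sizes. The 3 measured seed storage genes lie above 0 and passed, and 5 of 7 senescence genes lie below 0 and passed.

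Jasmonate, flavonoid and auxin genes moved singly without their lists passing. Of 12 measured jasmonate and wound genes 6 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.116): LOX2, a lipoxygenase gene of jasmonate synthesis, rose by 1.87 ± 0.11 (adjusted p = 1.3e-07), and the regulator gene MYC2 by 0.98, while PR4 fell by 1.39; the probe set of VSP1, which may match other genes, was Absent on all wild-type arrays, had a mutant signal of 218 ± 11.2 (SD, n = 3) and was called higher (adjusted p = 0.00617). Of 5 measured flavonoid genes 3 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.149): TT4, the chalcone synthase gene, rose by 2.62 ± 0.17 (adjusted p = 2.2e-07), F3H by 1.06 and FLS1 by 0.75, and TT7 fell by 1.06. Of 12 measured auxin genes 4 fell and none rose, also adjusted over the list alone (camera, adjusted p = 0.0638): besides GH3.3, WES1 fell by 1.89 (adjusted p = 2.7e-05), IAA29 by 1.02 and IAA2 by 0.67. The jasmonate list passed without wild-type array 3 (adjusted p = 0.047), and the auxin list without mutant array 3 (0.044), without wild-type array 1 (0.0126), with array weights (0.0294) and with no filter (0.0411).

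Of 9 measured flowering genes, FT, which encodes the mobile signal that induces flowering, was Absent on all wild-type arrays and Present on all mutant arrays, with a mutant signal of 324 ± 83.4 (SD, n = 3), and was called higher (adjusted p = 0.00544), and SEP3, a floral organ identity gene, fell by 0.85 (log2, adjusted p = 0.00109); adjusted over the list alone, 1 rose and 2 fell (camera, adjusted p = 0.325). Of 9 measured gibberellin genes, GA3OX1, a synthesis gene, rose by 1.08 and GASA1 fell by 1.29, also adjusted over the list alone (camera, adjusted p = 0.928). Of 13 measured salicylic acid and defence genes, PR5 (0.97) and WRKY33 (0.56) rose and PR1 fell by 1.22, also adjusted over the list alone (camera, adjusted p = 0.942). Of 27 measured photosystem and Rubisco genes 2 rose and 3 fell, also adjusted over the list alone (camera, adjusted p = 0.21), with NPQ4 rising by 0.91 ± 0.13, PSBO2 by 0.47, and PSAN and PSBX falling by 0.44 and 0.41. AS1 was the only measured leaf polarity gene and differed by 0.15 ± 0.25 (adjusted p = 0.695).

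**Figure D3:**
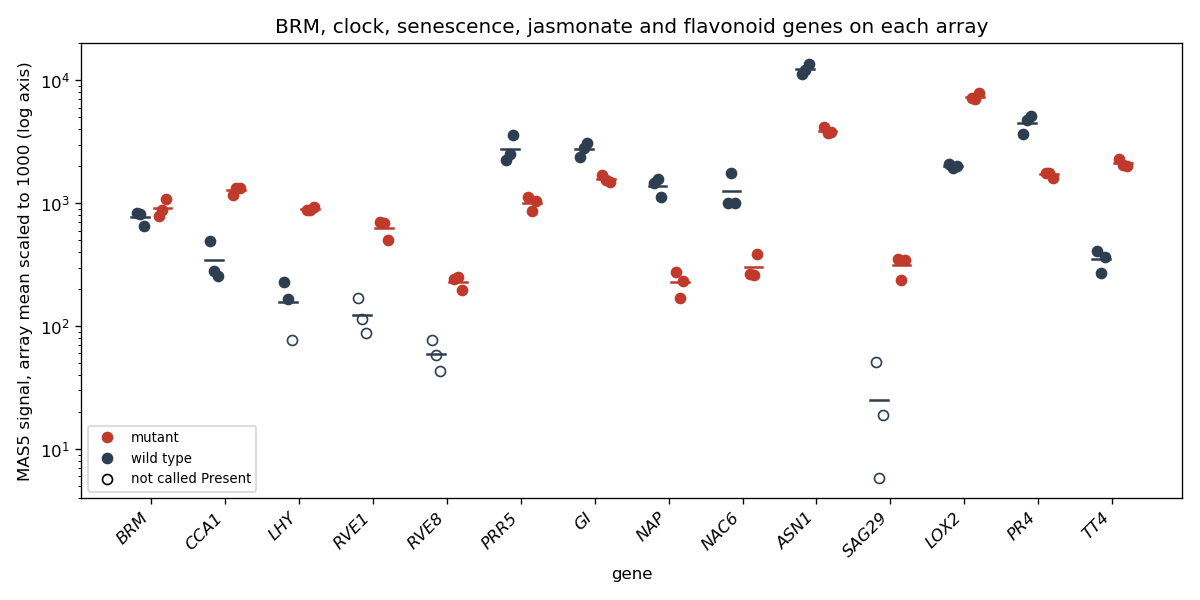
Signal on each array (log axis, array mean scaled to 1000) for BRM and for clock, senescence, jasmonate and flavonoid genes, with 3 mutant and 3 wild-type points per gene, open where not called Present, and a line at each group mean. BRM overlaps between the groups, with means of 917 and 768.

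Markers of another cell type moved with the groups. Of 3 measured guard cell genes 2 fell and none rose, also adjusted over the list alone (camera, adjusted p = 0.0423; adjusted p = 0.254 with an estimated correlation): MYB60, a guard cell transcription factor gene, by 1.31 (adjusted p = 0.000475) and KAT1, a guard cell potassium channel gene, by 1.02 (adjusted p = 0.00227). Without mutant array 1 the guard cell list no longer passed (adjusted p = 0.0562), nor with no filter (0.505), the stricter Present filter (0.0504) or a spread prior without trend (0.0621). Of 13 root markers 2 were measured: SCR rose by 0.58 (adjusted p = 0.0101), and PYK10 differed by -0.29 ± 0.12 (adjusted p = 0.105) and was called lower only when adjusted over the list alone. The control probe set for 25S ribosomal RNA was far lower on the mutant arrays, at 439 ± 59.9 (SD, n = 3) against 5579 ± 1947 (SD, n = 3). The ratio of 3-prime to 5-prime ubiquitin signal was 1.58 ± 0.12 (SD, n = 3) in the mutant against 1.09 ± 0.30 (SD, n = 3) in the wild type. An older ubiquitin probe pair overlapped between the groups, at 2.84 ± 0.19 (SD, n = 3) against 2.62 ± 0.25 (SD, n = 3).

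Per the array codes in the file headers, the 3 mutant arrays and the 3 wild-type arrays belong to different array series, so batch and genotype cannot be told apart for any value above. Of the 73 named genes that passed, 53 kept their call whichever array was left out. The other 20 lost it without at least 1 array, with a highest adjusted p between 0.0542 and 0.194: SESA2, AT2G27420, GH3.3, AT3G24450, LEA14, DRIP2, PSBO2, PSBX, PR1, PR5, WRKY33, MYC2, CBF2, HAB1, IAA29, MCM2, CYCD3;1, FLS1, STZ and TCH4.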

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

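The tests on 25S ribosomal RNA were chosen after the results were seen, as were the counts of other splits for probe sets; those for lists were fixed beforehand.

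On control probe sets, which no comparison used, all 3 mutant arrays lay above all 3 wild-type arrays in 5 measures. The ratio of 3-prime to 5-prime ubiquitin signal had a mutant mean 1.46 times that of the wild type. The added bacterial transcripts bioB, bioC, dap and phe had mutant means 1.27, 1.18, 1.31 and 1.47 times those of the wild type.

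The 25S ribosomal RNA signal was 12.3-fold lower on the mutant arrays (log2 difference -3.62). A preparation or priming step that lost RNA without long poly(A) tails in general is argued against as the whole cause only if it took such RNAs by like amounts, which was not tested. The 55 plastid-encoded probe sets had a median log2 fold change of -0.35 (quartiles -0.74 and -0.083). Of them 26 fell and 2 rose, while of all 14313 tested 1908 fell and 1965 rose, so a smaller loss stays open. RNA degradation may differ between the groups. Of the 3-prime to 5-prime ratios of actin, GAPDH and ubiquitin, 1 of 3, that of ubiquitin, separated the groups. The older probe pairs of the same 3 transcripts all overlapped between the groups, so degradation stays open. The array series and the genotype coincide, and an effect of the mutation on ribosomal RNA was not tested.

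With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3873 probe sets past the threshold and the highest of the others 0; for changes of at least 2-fold it gave 976 against 0, and for gene lists 7 against 4. In each case 1 of the 10 splits, the real one, gave a result as large. Every other split mixes arrays of both groups, so a difference between the groups widens the spread within it and lowers its count. The low counts there therefore add no support of their own. By limma, 5449 probe sets had an unadjusted p under 0.05 in the real split.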

How the results depend on the processing

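The alternatives in this section were fixed before the data were examined. The count of 3873 probe sets stayed within 1.5 times under all alternatives except the stricter threshold of 0.01, which gave 2112 by construction; the range without single arrays was 2657 to 3639. The count of 976 with at least a 2-fold change stayed within 1.5 times throughout (907 to 1139 without single arrays). BRM did not pass under any alternative (adjusted p 0.188 to 0.651; log2 0.12 to 0.36 without single arrays). Calls shared with the reported ones had the same direction in every alternative. Of the 7 lists past the threshold, 4 remained in number with the filter of Present on all 3 arrays of a group and 4 with the spread prior without trend, 0 with an estimated correlation, and 4 to 8 without single arrays (4 without mutant array 1). The cause was not tested. The estimated correlation was above the preset 0.01 for senescence (0.032), cold (0.041) and morning clock (0.83). It was below 0.01 for seed storage (-0.088), cell division (-0.018), touch (-0.015) and guard cell (-0.24), so a higher correlation does not account for their lost calls. Seed storage, cell division, senescence and morning clock passed in the 16 alternatives that kept the preset correlation of 0.01, which therefore do not test that setting. A Present filter, which set the direction of the seed storage result, was kept in all of these but the setting with no filter. The count of 7 lists with no filter lacks the cold and guard cell lists. It holds the auxin and heat shock lists, the latter testable only there. By fry, which does not compare a list with other genes, 10 lists passed. Deviations of same-numbered arrays correlated at 0.015, -0.0065 and 0.047, which gives no sign of pairing by replicate number but cannot exclude it. Array weights were highest for replicate 2 and lowest for replicate 3 in both groups. They were 1.75 and 0.678 in the mutant and 1.49 and 0.596 in the wild type. With the replicate block 3699 probe sets, 963 with at least a 2-fold change and 7 lists passed, and BRM stayed at 0.25.

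Among the 81 named genes tested, 1 lost its call under the block (AT3G24450), 8 with no filter and 16 with the spread prior without trend; 20 of 73 calls were lost without some array. Without single arrays, OLEO3 ran from -0.99 to 0.17 and AS1 from -0.059 to 0.48, neither passing. Lists that turned direction never passed: SWI/SNF subunits had adjusted p of 0.88 with no filter, 0.966 without trend, 0.902 with array weights, 0.962 with the replicate block, 0.774 by fry and 0.762 to 0.99 without single arrays; Polycomb 0.88 with no filter and 0.676 to 0.99; salicylic acid 0.902 with array weights, 0.965 by fry and 0.648 to 0.946; gibberellin 0.88 with no filter and 0.648 to 0.965; embryo transcription factors 0.664 to 0.965. Signal near the lowest Present level limits the dim seed genes, whose folds are bounds.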

Other observations

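The iron, copper and plastid gene sets and their tests were chosen after the results were seen; the second set of clock genes and its test were written before its values were seen.

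Genes of iron supply moved together in these leaves. All 11 measured members of a chosen set of 13 genes known to be induced by iron deficiency rose, and also on 6 of 6 choices of the array left out. The set does not hold every such gene. The set was put together after 7 of them had been seen to rise, so it was tested on the other 4, PYE, BTS, FRO3 and NRAMP4, which all rose (camera, adjusted p = 2.8e-06; adjusted p = 0.0415 with an estimated correlation). Besides bHLH39, BHLH101 and AT1G47400, a gene of a small peptide of the iron response also called IMA1, they included OPT3, a phloem metal transporter gene (2.95 ± 0.15, log2, SE; limma, adjusted p = 2.3e-08), ZIF1, a vacuolar transporter gene (2.95 ± 0.12, adjusted p = 9.6e-09), NAS4, of nicotianamine synthesis (3.43 ± 0.40), BTS (2.48 ± 0.14) and NRAMP4 (2.02 ± 0.12). Of 6 measured iron storage and excess genes 5 fell; without FER1, seen beforehand, 4 of 5 fell (camera, adjusted p = 0.000225; adjusted p = 0.0874 with an estimated correlation). FER1, a ferritin gene, fell by 2.81, FER4 fell by 1.93, YSL1 fell by 1.62, VTL2 fell by 0.98 and FER3 fell by 0.83.

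Copper enzyme genes fell as well. Of 4 measured copper superoxide dismutase genes, CSD2 fell by 2.91 (limma, adjusted p = 1.2e-08), CSD1 by 2.11 (adjusted p = 1.3e-06) and CCS, their copper chaperone gene, by 1.38, while CSD3 differed by -0.39 (adjusted p = 0.088; camera for the set without CSD2, seen beforehand, adjusted p = 0.000769, and adjusted p = 0.0854 with an estimated correlation). Genes induced by copper deficiency went both ways: COPT2 rose by 1.21 and CCH by 0.62, and FSD1, the iron superoxide dismutase gene, fell by 0.80 (camera, adjusted p = 0.523).

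For the iron pattern, root tissue could dilute the leaf RNA and lower the storage genes. Their median was -1.30, while the lower quartile of the photosystem and Rubisco genes was -0.20. Those leaf genes are among the brightest on the arrays, where a fall may show less, so the quartile alone cannot decide. The dimmest of them in the wild type, NPQ4 (14247.6) and PSBO2 (14302.5), rose by 0.91 and 0.47, and PSBW and PSAN fell by 0.33 and 0.44. FER1 stood at 19573.6 in the wild type. At such signals, dilution by as much as the storage genes fell is argued against. For the rise, root tissue stays open, since the 95% interval of PYK10 ended at -0.020 and IRT1, a root iron transporter gene, was Present on 0 mutant arrays, yet the wild-type PYK10 signal of 2986 would hide a small share of root. Another iron supply in the medium may also give this pattern. The labels give 1 medium for both groups but not whether their plates were made together. The storage gene median of -1.30 (-0.98 without FER1) cannot tell another iron supply from an effect of the genotype. An effect of the mutation on iron response is a hypothesis that was not tested separately.

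For the morning clock genes, harvest at another hour may account for the rise. In a second set of clock-controlled genes 5 of 8 morning genes rose (camera, adjusted p = 0.000115; adjusted p = 0.223 with an estimated correlation) and 2 of 3 evening genes fell (camera, adjusted p = 0.0414; adjusted p = 0.294 with an estimated correlation). The median log2 fold change was 1.04 over 8 morning genes and -0.87 over 3 evening genes, a difference of 1.92 (one-sided exact permutation over genes, p = 0.0242; genes are not independent replicates, and the FKF1 probe set may match other genes). RVE2 rose by 2.67, COL2 by 2.28 and CDF1 by 1.78, and CAT3 fell by 0.88, while LNK2 stood at 0.026 (adjusted p = 0.934) and PRR3 at 0.048 (adjusted p = 0.921). A change of the clock in the mutant at the same hour predicts the same difference of 1.92, so these 2 explanations cannot be told apart.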
